A study of Mus musculus with 12 samples.

How the data were processed

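RNA from the livers of 12 male C57Bl/6 mice was measured on Affymetrix whole-transcript arrays, 1 array per animal. Per the labels, wild-type mice and mice lacking Hdac6 received vehicle or dexamethasone at 1 mg/kg by intraperitoneal injection over 3 weeks. The 4 groups held 3 animals each, all separate animals. The labels give no dose for the vehicle, no date of hybridisation and no time of tissue collection.

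The deposited values are on a log2 scale, with 1 column per array and 34760 probe sets. Their range of 0.927 to 13.5 fits base 2 under the ceiling of a 16-bit scanner, and natural or base-10 logarithms would exceed it. The authors processed the arrays in R 2.10.0 with the affy package, per the submitters' processing notes. The sorted values of the 12 arrays differed from their mean by at most 0.215, which shows a normalisation between arrays. The method of background correction, normalisation and summarisation is not given in the sources used here.

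Gene symbols came from the probe annotation supplied with the series. Of the probe sets, 21640 carried 1 symbol, 1321 several and 11799 none. The 1-symbol probe sets covered 19937 genes, and the probe set with the highest mean over the 12 arrays stood for a gene with more than 1 (954 genes). A gene was kept if its value exceeded the 20th percentile of its array in at least 3 of the 12 arrays, which left 17904 genes. Probe sets with several genes or none were tested separately and not named. The RefSeq gene table of assembly GRCm38.p6 served only for current symbols, of which it changed 0, and for the order of neighbouring genes; 21553 of the 1-symbol probe sets had their gene in it.

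Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (tables with the package data.table, version 1.17.8), with empirical Bayes moderation of the variance. The fit had 8 residual and 5.07 prior degrees of freedom, and the median residual SD per gene was 0.143 on the log2 scale. For arrays, their number limits the precision. The 7 comparisons were dexamethasone against vehicle in each genotype, knockout against wild type under each treatment, the difference of the dexamethasone effects (knockout minus wild type, the interaction) and both effects averaged over the other factor. The p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Errors of log2 changes are standard errors from this fit, and errors of group levels are SD.

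Gene lists for pathways and cell types, the comparisons, the tests, the named-gene rule and most alternatives were fixed before the data were examined. A list of 5 genes that can differ between mouse strains was set aside for description only. Each of the 43 other lists with at least 3 measured members was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated per list, and fry, which asks whether a list's genes moved on balance one way, were run beside it. Counts of list members were taken from adjustment over all genes, and also adjusted over the list alone.

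Attenuation of the response in the knockout was measured as the median interaction over genes that passed the threshold in the averaged dexamethasone effect, each signed by that effect. Its p-value came from limma's roast with 9999 rotations, on both sides. In this balanced design the average and the interaction are uncorrelated estimates, so the choice of genes favours neither genotype.

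The genes named below follow a rule: Hdac6 in comparisons of genotype; Pck1, G6pc, Tat, Ppargc1a, Fkbp5, Tsc22d3, Per1 and Igfbp1 in the dexamethasone comparisons and the interaction; and up to 10 genes with the largest increase and 10 with the largest decrease past the threshold whose groups did not overlap, predicted genes left out. Where fewer than 3 genes passed, the 10 with the smallest p were taken. For each list described, up to 4 members with the smallest p were added, with members already named. Genes named outside the rule are said to be.

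The fit was tested on simulated data with 17904 genes. At a true log2 change of 1 in the wild-type dexamethasone comparison, 89.9% of 200 changed genes per simulation were recovered, and at 0.5, 50.1%; of the calls, 4.8% were false. For the interaction the recovered shares were 71.3% and 13.7%. For the averaged dexamethasone effect they were 96.1% and 79.1%. A knockout response set to 0.8 of the wild type gave a mean median interaction of -0.145 and a roast p under 0.05 in 10 of 10 simulations, and an equal response did so in 0 of 10. Only genes with a large averaged dexamethasone effect were given a response there. The simulated noise was independent between genes, unlike that of real arrays. The 10 of 10 is therefore no measure of the power to detect such a difference in these data.

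The alternatives were no filter and a filter at the 50th percentile, quantile normalisation, arrays centred on their median, cyclic loess, the mean of a gene's probe sets, moderation with trend and robust options, array weights, the replicate number as a block, the 6 arrays of a comparison alone, and leaving out each array in turn. After the data were seen, 2 more were added: leaving out 4 arrays that carried pancreas transcripts, and a score of those transcripts as a covariate. Results were also recounted over other splits of the arrays, all 10 for 3 against 3 and 100 random draws otherwise.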

Results

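Liver messenger RNA was profiled in 12 male mice, 3 animals in each of 4 groups: wild type with vehicle, wild type with dexamethasone, Hdac6 knockout with vehicle and Hdac6 knockout with dexamethasone. Dexamethasone is a synthetic glucocorticoid. Hdac6 encodes a mainly cytoplasmic deacetylase whose known substrates include tubulin and the chaperone Hsp90. The design asks what the drug does to liver transcripts in each genotype and whether the response differs without Hdac6. Values are deposited log2 intensities, so a difference of 1 is a doubling, and each group level below is a mean over n = 3 arrays. The 12 arrays had medians of 3.132 to 3.239. Pairs of arrays correlated at 0.9846 to 0.9912 within groups and at 0.9739 to 0.9914 between groups, and the first principal component, with 48.2% of the variance, separated the 6 dexamethasone arrays from the 6 vehicle arrays.

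Hdac6 (probe set 10603387) was lower in each of the 6 knockout arrays than in each of the 6 wild-type arrays. Its level was 6.20 ± 0.20 (SD) in wild-type vehicle livers and 4.12 ± 0.26 in knockout vehicle livers, a log2 change of -2.08 ± 0.14 (SE), 4.22-fold lower with an adjusted p of 3.70e-05. Under dexamethasone it was 5.99 ± 0.17 in wild type and 3.75 ± 0.14 in the knockout, 4.70-fold lower (-2.23 ± 0.14, adjusted p = 1.53e-05). Transcripts of the exocrine pancreas stood out in 4 arrays: wild-type vehicle 1 and 2, wild-type dexamethasone 3 and knockout vehicle 3. All 12 measured pancreas markers were higher in these 4 arrays than in the other 8, by 3.18 to 7.69, with a mean of 10.75 against 3.23 for the carboxypeptidase Cpa1 and 10.48 against 3.62 for the chymotrypsinogen Ctrb1. These arrays are spread unevenly over the groups, so many counts below are also given without them, which leaves 1 wild-type vehicle array whose spread is assumed to equal that of the others.

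**Figure D1:**
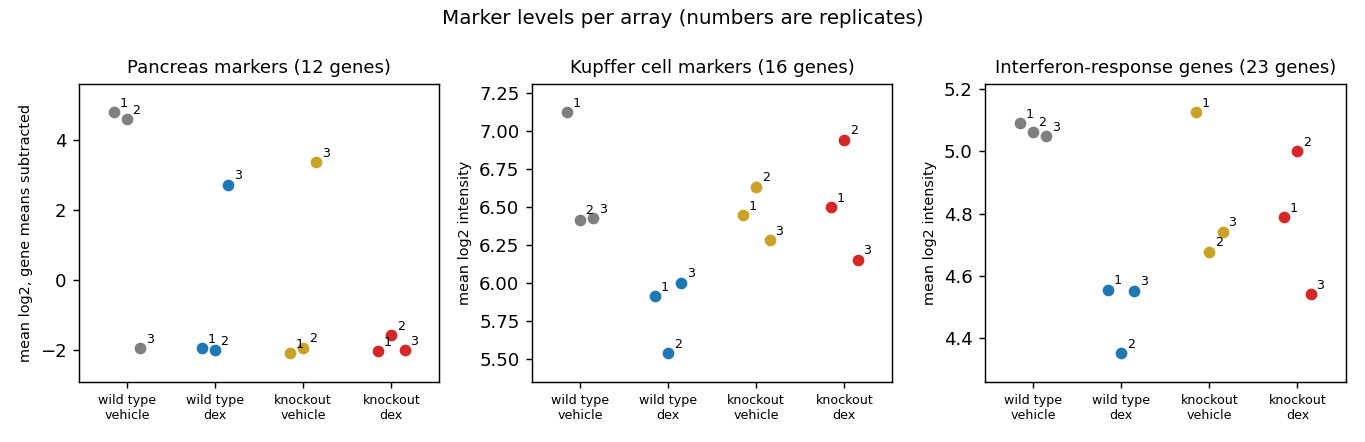
Each point is 1 array, numbered by replicate, in the 4 groups. The left panel shows the mean log2 level of 12 pancreas markers after subtracting each gene's mean, the middle panel the mean log2 intensity of 16 Kupffer cell markers and the right panel that of 23 interferon-response genes. The pancreas score was 4.78, 4.59, 2.72 and 3.37 in 4 arrays and below 0 in the other 8.

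Dexamethasone raised a set of liver genes by very large factors in wild-type mice. Sult1e1, an oestrogen sulfotransferase, went from 2.26 ± 0.09 (SD) to 9.40 ± 0.48, a log2 change of 7.13 ± 0.23 (SE). Its vehicle level lay near the arrays' 20th percentiles of 2.17 to 2.23, so it was at least 140-fold higher, and its place among the increases rests on a level near background. Cyp2b10, a drug-metabolising cytochrome P450, rose 121-fold (6.91 ± 0.58), Lcn2, an iron-binding acute-phase protein, 84.3-fold (6.40 ± 0.16), and the metallothionein Mt2 60.9-fold (5.93 ± 0.14). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 32.2-fold (5.01 ± 0.22). Fam107a (6.49), Gadd45b (5.83), Gadd45g (5.34), Ddit4 (4.48) and Mt1 (4.10) made up the rest of the 10 largest increases. The steepest decreases were in Arrdc3, an arrestin-family gene (-3.75 ± 0.26), Nr1d1, a repressor of the circadian clock (-3.59 ± 0.45), the tight junction gene Cldn1 (-2.96 ± 0.46) and Osgin1 (-2.90 ± 0.17). Fam13a (-2.72), Depp1 (-2.42), Gatm (-2.27), the first enzyme of creatine synthesis, Mid1ip1 (-2.22), Dclk3 (-2.18) and the interferon-linked transcription factor Irf1 (-2.09) followed; second probe sets for Mid1ip1 (0.10) and Irf1 (0.01, at a level of 2.74) did not share the decrease. Their adjusted p-values ran from 4.56e-11 for Mt2 to 3.88e-03 for Depp1. In limma, 819 genes were higher and 1245 lower past the threshold, of 17904 tested (657 and 1551 with arrays centred on their median), with 222 and 201 of them changed at least 2-fold. The groups did not overlap for 2037 of the 2064 genes and for 27% of all genes, where chance gives 10% for 3 against 3. Genes without overlap keep their sign whichever arrays are left out, so a kept sign says little about the arrays with pancreas transcripts. Leaving out the 4 arrays with pancreas transcripts gave 559 genes, 531 of them among the 2064, and all 2064 kept their sign; Cldn1 (-2.90), Depp1 (-2.96) and Mid1ip1 (-1.83) lost their calls.

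Genes known to be induced by glucocorticoids rose as a group: of 31 measured, 25 were higher and 1, Arrdc3, lower (26 and 1 adjusted over the list alone). Beyond those above, Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose 3.09-fold (1.63 ± 0.17), the clock gene Per1 1.90-fold (0.92 ± 0.20), Tat, which opens tyrosine breakdown, 2.04-fold (1.03 ± 0.15), and Igfbp1, an IGF-binding protein, 7.50-fold (2.91 ± 0.59). The list passed camera with an adjusted p of 4.26e-34, and this call held with an estimated correlation (adjusted p = 5.12e-05). With the 4 arrays with pancreas transcripts left out, 19 were higher and 1 lower, and Per1 (0.62), Tat (1.03) and Igfbp1 (2.35) were no longer past the threshold.

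Gluconeogenesis genes were higher: 5 of 18 passed and 0 were lower (9 and 0 adjusted over the list alone), with a mean log2 change of 0.38. The transcription factor Foxo1 rose by 1.24 ± 0.13, the glucose-6-phosphate transporter Slc37a4 by 0.76 ± 0.09, pyruvate carboxylase Pcx by 0.69 ± 0.12 and the coactivator Ppargc1a by 1.09 ± 0.20. Pck1, phosphoenolpyruvate carboxykinase, rose 1.82-fold, from 11.14 ± 0.20 (SD) to 12.00 ± 0.08 (0.87 ± 0.21 SE, adjusted p = 0.0149). G6pc, the glucose-6-phosphatase subunit, missed the threshold (0.89 ± 0.33, adjusted p = 0.108), with wild-type vehicle arrays at 9.91, 8.36 and 9.96, and was at 0.36 without wild-type vehicle 2. The list passed camera (adjusted p = 8.78e-05; adjusted p = 0.206 with an estimated correlation). In the 8 arrays free of pancreas transcripts 3 genes stayed past the threshold and Pck1 (0.62) and Pcx (0.64) lost their calls, as Pck1 did without wild-type vehicle 1 or 2 or wild-type dexamethasone 2, at 0.80 to 0.84.

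Lipid and sugar storage genes moved in several lists. Of 19 lipid droplet and lipase genes 7 were higher and 2 lower (7 and 4 adjusted over the list alone), among them the droplet coat genes Plin5 (3.39 ± 0.14) and Plin4 (2.67 ± 0.21) and the lipase Pnpla2 (0.98 ± 0.14). Of 28 fatty acid oxidation genes 10 were higher and 1 lower (10 and 3 adjusted over the list alone), including Acot1 (2.02 ± 0.11), an acyl-CoA thioesterase, and Cyp4a10 (1.19 ± 0.21) and Cyp4a31 (1.43 ± 0.28), fatty acid hydroxylases. Of 17 glycolysis and glycogen genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone): the glycogen-targeting phosphatase subunits Ppp1r3c (2.85 ± 0.30) and Ppp1r3b (1.53 ± 0.22), Pfkfb3 (2.75 ± 0.37) and the glycogen synthase Gys2 (0.56 ± 0.14). Cholesterol synthesis genes were lower, 5 of 19 past the threshold and 0 higher (8 and 0 adjusted over the list alone), with Stard4 at -0.89 ± 0.16 and Insig1 at -1.22 ± 0.22. Camera gave adjusted p-values of 0.0182, 4.00e-04, 5.06e-03 and 4.00e-04 in this order; with an estimated correlation the adjusted p-values were 0.218, 0.330, 0.210 and 0.616. Leaving out the arrays with pancreas transcripts, 5 droplet, 4 oxidation and 3 glycogen genes kept their calls as higher, and 1 droplet gene and 0 cholesterol genes theirs as lower. The called cholesterol genes kept their sign, with Insig1 at -1.03 and Stard4 at -0.58, while that list's mean moved from -0.46 to -0.11, and Gys2 also lost its call without wild-type vehicle 2 (0.40) or wild-type dexamethasone 2.

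Immune genes split. Acute-phase genes were higher, 8 of 23 and 0 lower (11 and 1 adjusted over the list alone), led after Lcn2 by Orm3 (2.88 ± 0.21), Saa4 (1.66 ± 0.14) and Saa1 (3.69 ± 0.34), which encode secreted acute-phase proteins. Interferon-response genes were lower, 14 of 23 with 2 higher (17 and 2 adjusted over the list alone): the chemokine Cxcl10 fell by 1.47 ± 0.17, the 2'-5' oligoadenylate synthetase-like gene Oasl2 by 0.92 ± 0.11 and the peptide transporter Tap1 by 1.39 ± 0.21, while Usp18, a brake on interferon signalling, rose by 1.79 ± 0.25. Kupffer cell markers were lower, 11 of 16 with 1 higher (13 and 1 adjusted over the list alone), with Cd5l at -1.55 ± 0.28, Csf1r at -1.03 ± 0.19 and Mpeg1 at -1.50 ± 0.29. Endothelial markers were lower for 8 of 16 and higher for 1 (11 and 2 adjusted over the list alone), with the VEGF receptor Kdr at -1.24 ± 0.14 and the hyaluronan receptor Lyve1 at 1.79 ± 0.17. Tubulin and cytoskeleton genes were lower for 7 of 13 and higher for 1 (the same adjusted over the list alone), with Tubb5 at -1.37 ± 0.20, Krt18 at -1.34 ± 0.22 and Tuba8 at 1.49 ± 0.26. These 5 lists passed camera with adjusted p-values of 4.52e-06, 5.70e-08, 9.50e-07, 8.78e-05 and 3.32e-03, and with an estimated correlation their adjusted p-values were 0.223, 0.223, 0.330, 0.223 and 0.223. Stellate (mean -0.26) and B-cell markers (mean -0.18) were lower too, with camera adjusted p-values of 0.0182 and 0.0477 (0.380 and 0.330 with an estimated correlation); both missed the threshold without wild-type vehicle 1 (-0.14 and -0.13) and without the 4 arrays with pancreas transcripts (-0.07 and -0.12). Of 43 lists, 16 passed camera, 1 with an estimated correlation and 17 in fry. Pancreas markers differed the same way (mean -2.88, camera adjusted p = 0.0167, adjusted p = 0.740 with an estimated correlation), and without the 4 arrays that carried them 6 acute-phase genes kept their calls as higher and 3 interferon, 0 Kupffer, 1 endothelial and 1 tubulin genes theirs as lower. With 1 wild-type vehicle array left, these lost calls came with the same sign and often similar changes: Cd5l (-1.48), Mpeg1 (-1.38), Csf1r (-0.74) and Tap1 (-1.48), the Kupffer mean being -0.70 against -0.83.

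In knockout mice dexamethasone raised many of these genes by similar factors. Cyp2b10 rose 177-fold (7.46 ± 0.58), Mt2 106-fold (6.73 ± 0.14), Lcn2 80.4-fold (6.33 ± 0.16), Sult1e1, from a vehicle level near background (2.23), at least 60.3-fold (5.91 ± 0.23) and Fkbp5 26.2-fold (4.71 ± 0.22). Gadd45b (5.83), Fam107a (5.76), Ddit4 (4.88), the lysophospholipid transporter Mfsd2a (4.82) and Mt1 (4.67) completed the 10 largest increases. Arrdc3 was 14.8-fold lower (-3.89 ± 0.26), Osgin1 14.2-fold (-3.82 ± 0.17), Nr1d1 6.50-fold (-2.70 ± 0.45) and Cldn1 5.21-fold (-2.38 ± 0.46), followed by the transcriptional regulator Id2 (-2.28), Rnf125 (-2.15), Depdc7 (-2.07), Rnf186 (-2.06), Tnfaip2 (-1.96) and the succinate receptor Sucnr1 (-1.94). In limma, 784 genes were higher and 701 lower past the threshold, 256 and 132 of them at least 2-fold. The groups did not overlap for 1471 of the 1485 genes and for 24.3% of all genes, where chance gives 10%. As in wild type, leaving out arrays cannot reverse the sign of these 1471. Omitting the 4 arrays with pancreas transcripts, 1045 genes passed, 957 of them among the 1485, and all 1485 kept their sign. Of 43 lists, 8 passed camera, 1 with an estimated correlation and 12 in fry.

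The gluconeogenic and acute-phase lists were also higher with dexamethasone in the knockout. Of 18 gluconeogenesis genes 7 were higher and 0 lower (8 and 1 adjusted over the list alone): Pck1 rose 2.62-fold, from 10.52 ± 0.49 (SD) to 11.90 ± 0.28 (1.39 ± 0.21 SE, adjusted p = 7.52e-04), Ppargc1a by 1.08 ± 0.20, Foxo1 by 1.17 ± 0.13 and Slc37a4 by 0.92 ± 0.09. G6pc did not pass (-0.29 ± 0.33, adjusted p = 0.757). Of 31 glucocorticoid-induced genes 24 were higher and 1, Arrdc3, lower (26 and 1 adjusted over the list alone), with Tat at 1.40 ± 0.15, Tsc22d3 at 2.46 ± 0.17, Per1 at 2.32 ± 0.20 and Igfbp1 at 2.12 ± 0.59, whose groups overlapped and whose call was lost without any of 8 of the 12 arrays, at 1.55 to 2.12. Of 23 acute-phase genes 11 were higher and 0 lower (the same adjusted over the list alone), including Saa1 (3.87 ± 0.34), Orm3 (3.35 ± 0.21) and Saa4 (1.70 ± 0.14). Lipid droplet genes were higher for 7 of 19 and lower for 1 (9 and 3 adjusted over the list alone), led by Plin5 (2.77 ± 0.14) and Plin4 (2.59 ± 0.21), and cholesterol synthesis genes were lower for 5 of 19 and higher for 0 (8 and 0 adjusted over the list alone), with Stard4 at -0.86 ± 0.16. Camera gave adjusted p-values of 1.16e-03, 1.98e-40, 7.61e-13, 0.0170 and 2.53e-05, and with an estimated correlation the adjusted p-values were 0.148, 2.65e-05, 0.148, 0.148 and 0.594. In the 8 arrays without pancreas transcripts 6 gluconeogenic, 23 glucocorticoid-induced, 11 acute-phase and 6 droplet genes kept their calls as higher and 1 cholesterol gene, Stard4 (-0.70), its call as lower; Insig1 (-0.77), Sc5d (-0.58) and Hmgcs1 (-1.06) were still lower without a call.

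Kupffer and interferon genes did not pass as groups in the knockout. Of the 16 Kupffer markers only the haemoglobin scavenger receptor Cd163 was higher (1.30 ± 0.28) and 0 were lower in limma (the same adjusted over the list alone), with a mean log2 change of 0.08 and a camera adjusted p of 0.785. Of the 23 interferon genes Usp18 (2.39 ± 0.25) and Irgm1 (1.16 ± 0.20) were higher and Cxcl10 (-1.30 ± 0.17) was lower, with a mean of -0.07 and a camera adjusted p of 0.326. In this comparison 4 of 14 male-biased liver genes were lower and 0 higher (5 and 1 adjusted over the list alone), with the P450 Cyp2u1 at -1.25 ± 0.16 and the steroid dehydrogenase Hsd3b5 at -1.18 ± 0.21; the list passed camera (adjusted p = 8.95e-03; adjusted p = 0.569 with an estimated correlation). With the arrays carrying pancreas transcripts left out, 1 Kupffer gene was higher and 0 lower (mean -0.01), 2 interferon genes were higher and 1 lower (mean -0.12), and 1 male-biased gene was higher and 2 lower (mean -0.15).

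**Figure D2:**
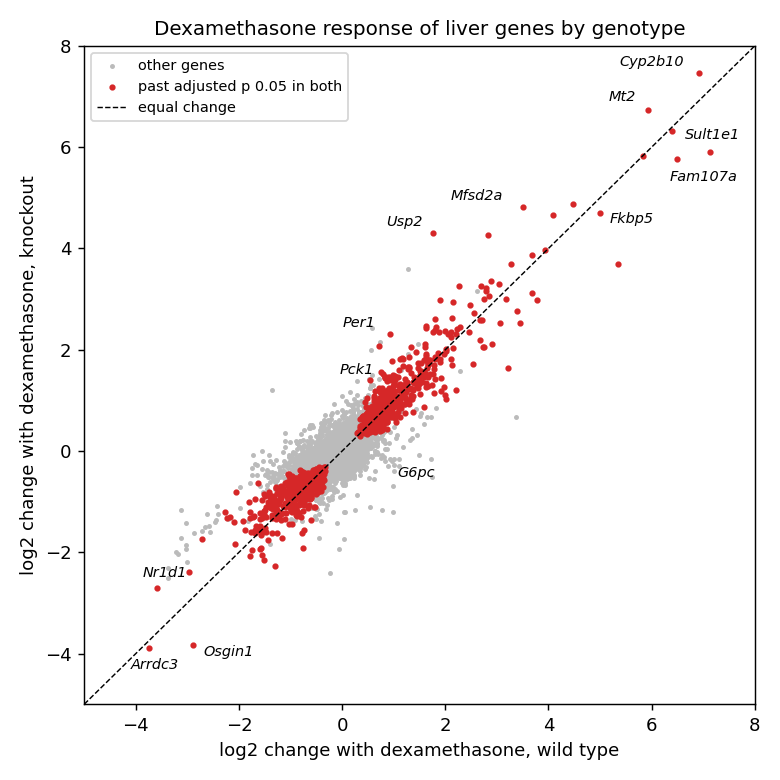
Each point is 1 of 17904 genes, with its log2 change under dexamethasone in wild type on the horizontal axis and in the knockout on the vertical axis. Red points passed the threshold in both genotypes, and the dashed line marks an equal change. Cyp2b10 lies at 6.91 and 7.46, Arrdc3 at -3.75 and -3.89, and the Pearson correlation over all genes was 0.81.

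The dexamethasone responses of the genotypes overlapped widely. Past the threshold in both genotypes, 534 genes were higher (35.9 would be shared by independent draws) and 500 lower (48.7 by independent draws), and in limma 0 genes were called in opposite directions. Of the genes called in wild type but not in the knockout, 1030 in number, 90.5% had the same sign in the knockout. Across the 2515 genes called in either genotype the log2 changes correlated at 0.908, and across all genes at 0.81; genes are not independent replicates. The 4 groups share no arrays, so these overlaps do not come from a common control. Both comparisons do share 1 variance estimate per gene, which the independent draws leave out. Pancreas markers also differed the same way in both, with means of -2.88 in wild type and -1.66 in the knockout.

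The test of the difference itself, the interaction, asked which genes responded differently without Hdac6. No gene passed in limma (0 at the adjusted threshold and 1109 at an unadjusted p under 0.05), and Pck1 (0.52 ± 0.29, adjusted p = 0.834), Tat (0.38 ± 0.22), Fkbp5 (-0.30 ± 0.32), Ppargc1a (-0.01 ± 0.28, 0.06 with arrays centred on their median), Tsc22d3 (0.84 ± 0.24), Per1 (1.39 ± 0.29, adjusted p = 0.337) and Igfbp1 (-0.79 ± 0.83) did not differ beyond the threshold. G6pc did not differ beyond it either (-1.18 ± 0.46, adjusted p = 0.754), and its interaction was -0.66 without wild-type vehicle 2, the lowest array of its group. For Ppargc1a a second probe set, at a mean level of 4.08 against 5.52, gave an interaction of -0.37 (unadjusted p = 0.272 in limma). The 10 genes with the smallest p, all short of the threshold, were Rasa3 (1.19, adjusted p = 0.0756), Acot1 (-0.98), Neurl3 (0.99), Fgl2 (1.16), Usp2 (2.54), Oasl2 (0.89), Map2k6 (1.37), Epsti1 (0.65), Tlr8 (0.98) and the glucose transporter Slc2a4 (-0.71). Usp2, Map2k6, Neurl3 and Per1 were already lower in knockout vehicle livers, by -2.88, -1.43, -0.90 and -1.52. Under dexamethasone they were not called between genotypes, so their interactions go with a lower start in the knockout. Acot1 was instead lower in the knockout under dexamethasone (-0.72). Leaving out 1 array gave 0 to 3 genes, with 3 without wild-type vehicle 3, 2 without wild-type vehicle 1 (Per1 at 1.66 and Usp2 at 3.00) and 1 without knockout vehicle 3 or knockout dexamethasone 3, and leaving out the 4 arrays with pancreas transcripts gave 1, the clock repressor Ciart (2.01), named after its value was seen.

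**Figure D3:**
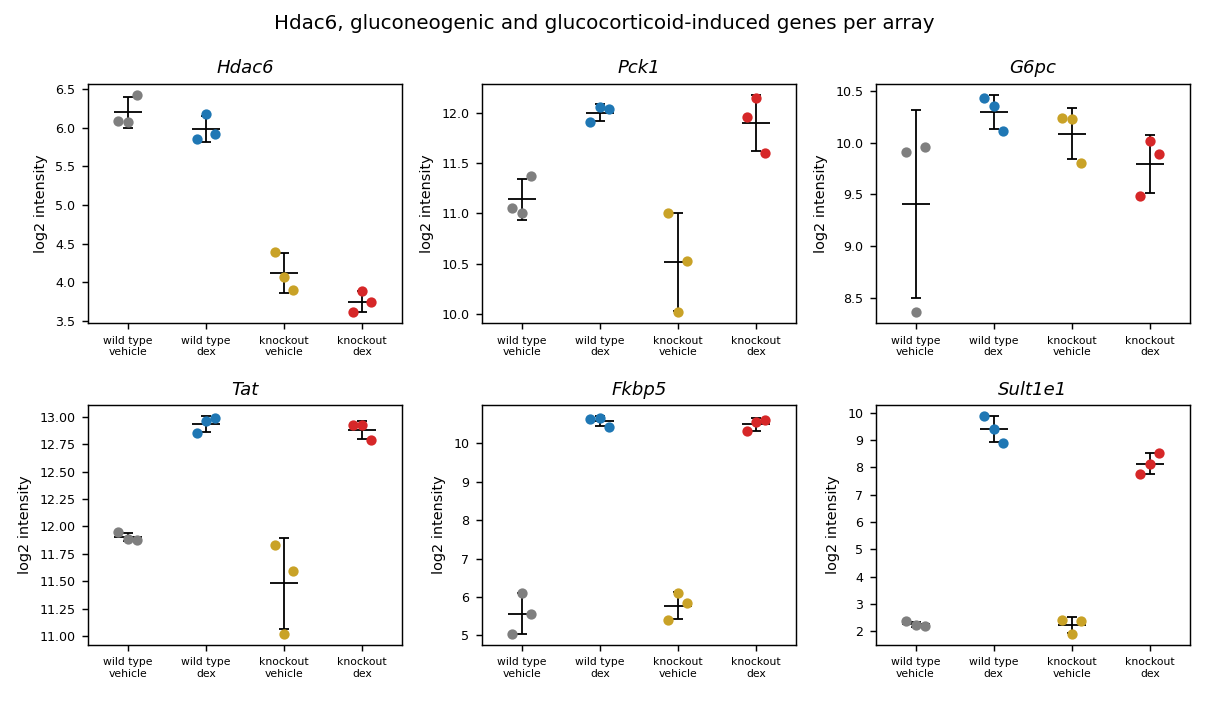
Points are the deposited log2 intensities of single arrays for Hdac6, Pck1, G6pc, Tat, Fkbp5 and Sult1e1, with the mean (horizontal line) and SD (bars) of the 3 arrays of each group. Hdac6 lies between 3.62 and 4.40 in the knockout arrays and between 5.86 and 6.43 in the wild-type arrays, and Pck1 rises with dexamethasone in both genotypes.

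Across the response as a whole, the knockout was not shown to respond less. Over the 3085 genes past the threshold in the averaged dexamethasone effect, the median response was 0.498 in wild type and 0.438 in the knockout on the log2 scale. The median interaction, taken as the attenuation of the dexamethasone response, was -0.0498 (quartiles -0.216 and 0.115), 57.9% of genes responded less in the knockout, and roast gave a p of 0.235. Raised genes had a median interaction of 0.0303 over 1306 genes and lowered genes one of -0.106 over 1779. Without knockout dexamethasone 1 the median was 0.0021, and without knockout dexamethasone 3 it was -0.0613 with the smallest p of any array left out, 0.047.

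Camera at its preset correlation set some gene groups apart in the interaction, and the other list tests did not. Kupffer cell markers, lower with dexamethasone in wild type, had a mean interaction of 0.91 over 16 genes, with 9 higher and 0 lower adjusted over the list alone, among them the scavenger receptor gene Cd68 (1.03 ± 0.24) and Cd5l (1.55 ± 0.39). Interferon-response genes had a mean of 0.51 over 23 genes, with 2 higher and 0 lower adjusted over the list alone, Oasl2 (0.89 ± 0.16) and the transcription factor Irf7 (1.10 ± 0.21). The endothelial list had a mean of 0.31. In these 3 lists, 0 genes passed over all genes in limma. Camera gave adjusted p-values of 5.31e-12, 4.56e-11 and 1.07e-06, and with an estimated correlation the adjusted p was 0.382 for each. Gluconeogenesis genes (mean -0.08, median 0.03, camera adjusted p = 0.638) and glucocorticoid-induced genes (mean 0.04, median 0, camera adjusted p = 0.648) did not pass. In all, 9 lists passed camera, 0 with an estimated correlation and 0 in fry. Leaving out the 4 arrays with pancreas transcripts, the Kupffer, interferon and endothelial means were 0.69, 0.47 and 0.29.

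Under vehicle, knockout and wild-type livers differed in few genes, and several of them belong to the circadian clock. Usp2, a clock-controlled ubiquitin protease, was 7.38-fold lower in the knockout (-2.88 ± 0.32, adjusted p = 4.25e-03), Per1 2.86-fold (-1.52 ± 0.20), Dbp, a clock output transcription factor, 2.61-fold (-1.39 ± 0.20) and Per3 2.30-fold (-1.20 ± 0.18). Fam47e (-1.50), the kinase Map2k6 (-1.43), uridine phosphorylase Upp2 (-1.06), Neurl3 (-0.90) and Mt2 (-0.84) were also lower. The choline kinase Chka (1.42), Dhrs9 (1.40), Slc45a3 (1.38), the tubulin Tubb2a (1.18), the decarboxylase Ddc (1.08), Asap2 (1.08) and the ferritin receptor Scara5 (0.77) were higher. Including Hdac6, 7 genes were higher and 11 lower in limma. The groups did not overlap for 18 of the 18 genes and for 11.8% of all genes, where chance gives 10%. Leaving out arrays therefore cannot reverse the sign of any of the 18. Leaving out the 4 arrays with pancreas transcripts, 3 of which are in this comparison, gave 5 genes, of which Hdac6, Usp2 (-3.32) and Slc45a3 (1.52) were among the 18; all 18 kept their sign. The count was 5 without wild-type vehicle 2, 8 without knockout vehicle 3, 10 without knockout vehicle 2 or knockout dexamethasone 2, and 28 without wild-type vehicle 1, while Hdac6, Usp2, Fam47e and Map2k6 passed whichever array was left out.

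The circadian list as a whole was lower in knockout vehicle livers: 4 of 17 genes fell and 0 rose (11 and 2 adjusted over the list alone), with a mean log2 difference of -0.63. Arntl, which peaks opposite to Dbp, was 1.42 ± 0.26 higher with an adjusted p of 0.095, and Nr1d1 did not pass (-0.01 ± 0.45). Camera gave an adjusted p of 2.07e-08 (adjusted p = 0.0632 with an estimated correlation) and fry 8.41e-03. In the arrays free of pancreas transcripts the mean was -0.82; of the 4 genes Usp2 stayed past the threshold, and Per1 (-1.77), Dbp (-1.70) and Per3 (-1.32) lost their calls with changes at least as large. Pancreas markers differed by -2.68 on average, the male-biased list by 0.18 (-0.28 without the 4 arrays), the fatty acid oxidation list by 0.13, and the stellate (-0.28), interferon (-0.22), endothelial (-0.17) and glycolysis lists (-0.09) were lower; these 7 also passed camera, 0 with an estimated correlation, and 2 lists of the 8 passed without wild-type vehicle 1. Gluconeogenesis genes did not (mean -0.07, camera adjusted p = 0.0793).

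**Figure D4:**
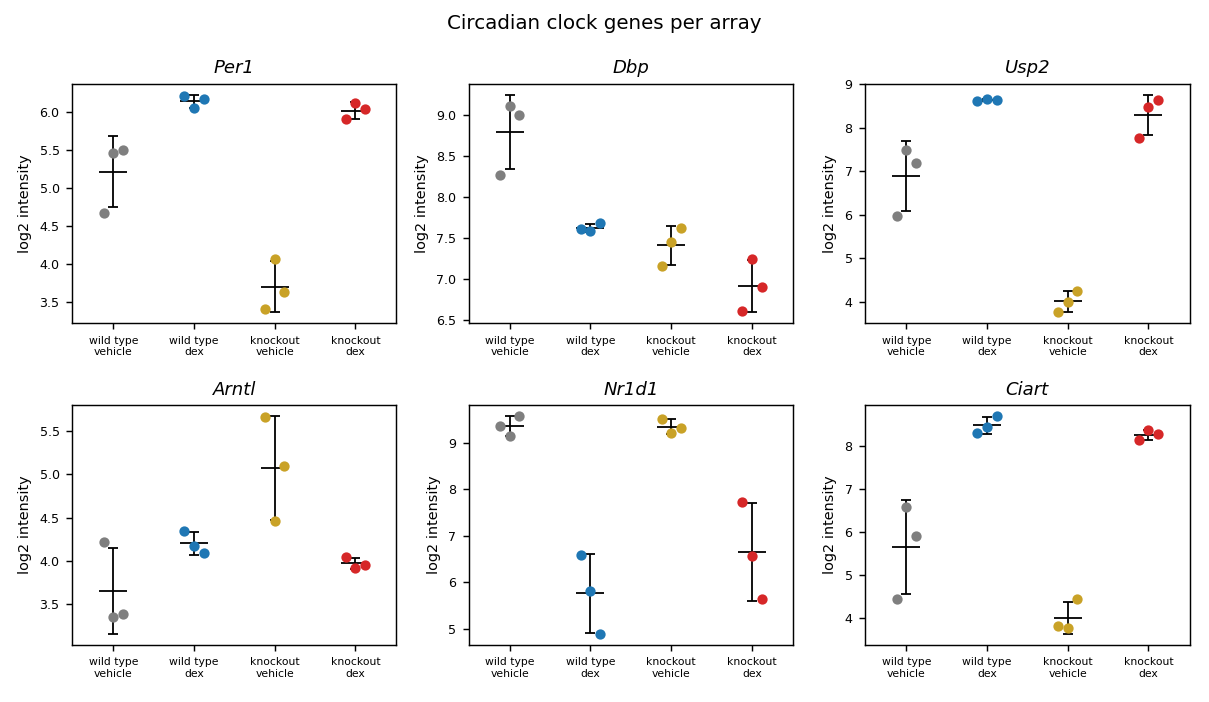
Points are the deposited log2 intensities of single arrays for 6 clock genes, with the mean (horizontal line) and SD (bars) of the 3 arrays of each group. Usp2 lies between 3.76 and 4.25 in knockout vehicle arrays and between 5.97 and 7.49 in wild-type vehicle arrays, and the groups meet at 7.77 to 8.66 under dexamethasone.

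Under dexamethasone, 5 genes differed by genotype. Saa2, an acute-phase apolipoprotein, was 9.46-fold higher in the knockout (3.24 ± 0.47, adjusted p = 0.0444), with arrays at 11.13, 10.35 and 9.05 against 7.56, 6.07 and 7.16 in wild type. Mdfic was higher (0.68 ± 0.10), and Hdac6, Gdap10 (-1.54 ± 0.17) and Acot1 (-0.72 ± 0.11) were lower. Limma called 2 higher and 3 lower, or 3 and 2 with arrays centred on their median, and all 5 had groups that did not overlap, against 14% of all genes and 10% by chance. Without overlap, the sign of these 5 cannot change when arrays are left out. Leaving out the 4 arrays with pancreas transcripts, Hdac6 alone passed, and all 5 kept their sign. The count was 2 without wild-type vehicle 2 or 3, wild-type dexamethasone 3, knockout vehicle 2 or 3 or knockout dexamethasone 1, 3 without wild-type dexamethasone 1, 1 without knockout dexamethasone 2 and 37 without knockout dexamethasone 3; of the 5 genes only Hdac6 passed in each case.

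Among the lists in this comparison, Kupffer markers were higher in the knockout by a mean of 0.71, with 13 of 16 higher and 0 lower adjusted over the list alone, such as Cd68 (0.73 ± 0.17) and Cd5l (1.14 ± 0.28), and in limma 0 passed over all genes. Acute-phase genes were higher by 0.38, with 1 of 23 past the threshold (5 higher and 0 lower adjusted over the list alone), including Steap4 (1.08 ± 0.21). Endothelial markers were higher by 0.14 (camera adjusted p = 8.57e-03; adjusted p = 0.387 with an estimated correlation). Interferon genes were higher by 0.29, with Oasl2 at 0.60 ± 0.11 and 4 higher and 0 lower adjusted over the list alone. Glycolysis and glycogen genes had a mean of -0.18, with pyruvate kinase Pklr at -0.70 ± 0.14 and 3 lower and 0 higher adjusted over the list alone. Gluconeogenesis genes had a mean of -0.16, with fructose-bisphosphatase Fbp1 at -0.30 ± 0.08. For the other 5 lists camera adjusted p-values were 6.41e-13, 2.42e-07, 4.51e-07, 7.26e-05 and 7.33e-03, and with an estimated correlation the adjusted p-values were 0.224, 0.224, 0.282, 0.112 and 0.224. Of 43 lists, 15 passed camera, 0 with an estimated correlation and 2 in fry. The gluconeogenesis list missed the threshold without wild-type dexamethasone 1 (-0.12) or knockout dexamethasone 3. In the arrays free of pancreas transcripts these 5 means were 0.80, 0.37, 0.32, -0.20 and -0.20, endothelial markers were at 0.13, and the acute-phase gene Saa2 lost its call with a change as large (3.35).

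Averaged over both genotypes, dexamethasone changed 3085 genes in limma, 1306 higher and 1779 lower, with Cyp2b10 146-fold higher (7.19 ± 0.41), Sult1e1, from levels near background, at least 91.9-fold (6.52 ± 0.16), Lcn2 82.3-fold and Mt2 80.5-fold. Pck1 was 2.18-fold higher (1.13 ± 0.15, adjusted p = 1.13e-04), and G6pc did not pass (0.30 ± 0.23, adjusted p = 0.470). Arrdc3 was 14.1-fold lower, Osgin1 10.3-fold, Nr1d1 8.85-fold, Cldn1 6.38-fold and Fam13a 4.69-fold, and Rnf152 fell by 1.95 ± 0.13. With the 4 arrays with pancreas transcripts left out 1695 genes passed, 1600 of them shared with the 3085. Averaged over both treatments, the knockout differed from wild type in 9 genes. Hdac6 was 4.45-fold lower (-2.15 ± 0.10, adjusted p = 3.02e-07), Usp2 was lower by a log2 change of -1.61 ± 0.22, Dbp -1.05 ± 0.14, Fam47e -1.02 ± 0.13, Gdap10 -0.99 ± 0.12 and Per3 -0.85 ± 0.13, and Ddc (0.80 ± 0.10), Mdfic (0.53 ± 0.07) and Tmem39a (0.44 ± 0.06) were higher. The split was 3 higher and 6 lower, or 5 and 6 with arrays centred on their median. Without the 4 arrays 3 genes passed, 2 of them among the 9, and single arrays moved the count to 5 without wild-type dexamethasone 3, 15 without wild-type vehicle 3, 21 without wild-type vehicle 1 and 29 without knockout dexamethasone 3.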

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

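The tests of explanations in this part were chosen after the results were seen, and the recounts over other splits of the arrays were set beforehand. Camera's test of the interaction itself set 9 lists apart, with mean log2 interactions of 0.913 for Kupffer markers, 0.509 for interferon genes, 0.308 for endothelial and 0.207 for stellate markers, 0.439 for the circadian list, 0.314 for cell cycle, 0.289 for acute-phase, -0.200 for fatty acid oxidation and -0.192 for male-biased genes. Without the 4 arrays with pancreas transcripts male-biased genes reversed (0.273), stellate markers fell short of the threshold (0.053), as did acute-phase genes (0.259), and fatty acid oxidation was at -0.347. Without wild-type vehicle 1 alone the stellate mean was 0.091. With an estimated correlation 0 of the 9 passed, and fry called 0. Among the 61 genes chosen for naming, 10 of them for the smallest interaction p-values, 4 had all 3 dexamethasone arrays above all 3 vehicle arrays in one genotype and below them in the other: Fgl2 (interaction 1.16), Epsti1 (0.65), Tlr8 (0.98) and Slc2a4 (-0.71). Their interaction in limma missed the threshold, with adjusted p-values of 0.250, 0.264, 0.264 and 0.264. Over all 17904 genes 72 had this arrangement (0.402%), against 89.5 (0.5%) by chance if no gene responded to dexamethasone. Genes that respond alike in both genotypes cannot show it, so that chance count is too high and the comparison cannot decide. The 4 genes were all among those 10 and missed the threshold, so opposite responses were not shown.

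In vehicle-treated knockouts, 11 clock genes that peak with Dbp were all lower than in wild type, with a mean log2 change of -1.14. Pancreas tissue in some arrays was argued against as the whole cause, since the mean stayed at -1.19 with the pancreas score as covariate, although 2 of the 4 genes past the threshold kept their calls. A candidate explanation is another clock phase at tissue collection. Under vehicle the 4 genes that peak opposite to Dbp (Arntl, Clock, Nfil3 and Cry1) had a mean change of 0.727. However, limma called 0 of them (2 at an unadjusted p under 0.05) and the labels give no collection time. Under dexamethasone the genes that peak with Dbp were also lower in the knockout arrays, at 6.26 to 6.53 against 6.60 to 6.75. The genes that peak opposite to Dbp were not higher there, at 5.83 to 6.05 against 6.01 to 6.19. The circadian list passed camera in that comparison (mean -0.19, adjusted p = 0.0469, adjusted p = 0.314 with an estimated correlation). Lower glucocorticoid action in the knockout liver stays open. The 29 induced genes outside the clock list went both ways, 16 lower and 13 higher, with a median of -0.0289 (quartiles -0.248 and 0.293). Usp2 and Per1 belong to both lists. Of all 31 induced genes 3 were called lower (Usp2, Per1 and Mt2) and 0 higher, and the list did not pass camera (adjusted p = 0.270). An effect of Hdac6 loss on the clock also stays open, as phase and genotype cannot be separated with 1 collection per animal.

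Kupffer markers fell with dexamethasone in wild type and not in the knockout, and the difference had a mean of 0.913. A single array high in the markers was argued against as the whole cause, since the mean was 0.68 without wild-type vehicle 1. Another share of non-parenchymal cells in the pieces stays open: endothelial and stellate markers together had an interaction of 0.257 (exact permutation p = 0.02). It was 0.175 (exact permutation p = 0.05) without wild-type vehicle 1. Without knockout vehicle 2 it was 0.206 (exact permutation p = 0.09), and without knockout vehicle 1 it was 0.266 (exact permutation p = 0.07). Taken singly, endothelial markers had 0.308 (exact permutation p = 0.02) and stellate markers 0.207 (exact permutation p = 0.345). Under dexamethasone stellate markers were lower in the knockout (-0.07) and Kupffer markers higher (0.71). T-cell (-0.054), NK (-0.052), cholangiocyte (-0.052) and B-cell markers (0.090) had small interactions, with exact permutation p-values of 0.28 to 0.745. The Kupffer list exceeded the endothelial and stellate markers by 0.656 (exact permutation p = 0.13). A chance difference between animals also stays open, with an exact permutation p of 0.05, or 0.516 adjusted over the 43 lists. These permutations exchanged genotype labels within each treatment. They are exact for no genotype difference under either treatment, so their p-values do not measure the interaction alone. A response of the macrophages that depends on Hdac6 was not tested apart from these explanations.

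Pancreas transcripts were high in 4 arrays of 3 groups. These arrays were singled out by 12 markers, so 16 exocrine genes outside that list were examined as well. Pancreatic tissue carried over with the liver is a candidate explanation, with a median difference of 1.37 for these genes between the 4 arrays and the other 8, and 9 of the 16 apart. Exocrine genes switched on in liver cells would be higher too, so this difference cannot tell these explanations apart. Such a switch in liver cells stays open as well, as the test on islet genes cannot decide. The 5 islet hormone genes were not higher in the 4 arrays (median difference -0.01). Their means in these arrays, 2.15 to 3.39, lay near or below the array medians of 3.132 to 3.239, and islets are a small part of the pancreas. A response to genotype or dexamethasone was argued against, since the marker mean ranged by 6.72 within the wild-type vehicle group.

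Other splits of the arrays were counted for each result. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. In wild type, 1 of the 10 splits, the real one, gave as many genes with dexamethasone (2064, highest other 1) and 1 as many lists (16, highest other 10). In the knockout these were 1 for genes (1485, highest other 0) and 4 for lists (8, highest other 12). For knockout against wild type under vehicle 2 splits gave as many genes (18, highest other 28) and 2 as many lists (8, highest other 9), and the split with 28 genes set the 3 arrays with pancreas transcripts against the other 3. Under dexamethasone 1 split gave as many genes (5, highest other 0) and 1 as many lists (15, highest other 12). Among 100 splits, only the real one reached the counts of the averaged dexamethasone effect, for genes (3085, highest other 385) and for lists (14, highest other 13). A share of 1 in 100 is under 0.05 and is the smallest these splits can give. The gene count stood far above the other splits, and the list count barely did. Chance was not excluded for the averaged genotype effect, with 5 splits for genes (9, highest other 23) and 13 for lists (11, highest other 13). Nor was it for the lists of the interaction, with 28 splits (9, highest other 14), or for attenuation, with 31 splits (-0.0498, farthest other -0.104). For genes of the interaction the real count was 0 in limma (1109 at an unadjusted p under 0.05), so all 100 splits gave as many (highest other 23) by construction and this recount decides nothing.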

How the results depend on the processing

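Leaving out the 4 arrays with pancreas transcripts and using their score as a covariate were chosen after the data were seen. Under quantile normalisation, cyclic loess, the stricter filter and the mean of probe sets, the gene counts, list counts, Hdac6 and the attenuation all stayed within 1.5 times their values or on their side of the threshold. Knockout against wild type under dexamethasone gave 3 genes in place of 5 with no filter, with the replicate number as a block (the numbers pair no animals) and with only the 6 arrays compared, where knockout against wild type under vehicle gave 9 in place of 18. The averaged genotype effect gave 14 genes in place of 9 with trend and robust moderation, 22 with array weights and 29 with the block. With arrays centred on their median the interaction of Ppargc1a was 0.062 in place of -0.01. Camera with an estimated correlation called 1, 1, 0, 0, 0, 1 and 0 lists for dexamethasone in wild type, in the knockout, genotype under vehicle, genotype under dexamethasone, the interaction and both averages, and fry called 1 for genotype under vehicle, 2 under dexamethasone, 0 for the interaction and 5 for the averaged genotype effect. Leaving out the 4 arrays, which leaves 1 wild-type vehicle array assumed to vary like the others, gave 559 genes for dexamethasone in wild type, 1695 for its average, 5 and 1 for genotype under vehicle and dexamethasone, 1 for the interaction, 3 for the averaged genotype effect, and 3 lists for genotype under vehicle. In that setting 10 values reversed: male-biased genes under vehicle (-0.28) and in the interaction (0.27), G6pc in the averaged dexamethasone effect (-0.001), and, by construction, the pancreas list in both averages (0.051 and 0.027), Reg1 in wild type with dexamethasone (0.042) and both averages (0.092 and 0.049), Clps in wild type with dexamethasone (0.013) and Try4 in the averaged genotype effect (0.046). The covariate gave 7 and 2 genes for genotype under vehicle and dexamethasone, and sets the pancreas list to 0 by construction, so that list was left out there. Of 576 other values 452 kept their direction and side of the threshold without the 4 arrays and 114 lost their call, and of 572 with the covariate 539 kept them. With single arrays left out, gene counts ran from 1417 to 2165 and 993 to 1603 for dexamethasone in wild type and knockout, 5 to 28 and 1 to 37 for genotype under vehicle and dexamethasone, 0 to 3 for the interaction, and 2628 to 3019 and 5 to 29 for the averages; list counts from 13 to 16, 7 to 13, 2 to 10, 11 to 16, 6 to 12, 12 to 16 and 11 to 15; Hdac6 from -2.22 to -2.10; and the attenuation from -0.0819 to 0.0021. The interaction ranged from -0.25 to 0.18 for Ppargc1a, -1.36 to 0.002 for Igfbp1 and -0.019 to 0.103 for glucocorticoid-induced genes, which ranged from -0.087 to 0.008 for genotype under dexamethasone. Of 271 calls of named genes, a gene counted once in each comparison, 98 were lost in at least 1 alternative and 0 reversed. In comparisons of 3 against 3 arrays nearly all called genes had groups without overlap. Leaving out arrays could not reverse those, so the 0 says little. Apart from the construction and the fewer arrays named, the cause of the changes was not tested. Signal over background limits genes near the lower end of the scale, such as Sult1e1 under vehicle.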

Other observations

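The lists in this part were picked for description after their values were seen, and the test of Hdac6's neighbours was set beforehand. Several lists held genes that changed with dexamethasone in both directions and did not pass camera. In wild type, Lpin1, a phosphatidate phosphatase, rose by 3.27 ± 0.17 and the lipogenic regulators Srebf1 and Mlxipl fell by 1.81 ± 0.26 and 0.70 ± 0.13; of 22 lipogenesis genes 4 were higher and 6 lower (5 and 6 adjusted over the list alone, mean 0.01, median -0.02, camera adjusted p = 0.767). In the knockout Lpin1 rose by 3.68 ± 0.17 and Thrsp by 2.99 ± 0.39, and Mlxipl fell by 0.95 ± 0.13, with 4 of the 22 higher and 3 lower (the same adjusted over the list alone). The insulin receptor substrate Irs1 fell by 1.55 ± 0.21 in the knockout (-0.80 with the mean of its probe sets), where 4 of 21 insulin and IGF genes were higher and 3 lower (5 and 5 adjusted over the list alone). Of 23 drug metabolism genes 4 were higher and 5 lower in wild type (4 and 9 adjusted over the list alone), and 4 higher and 0 lower in limma in the knockout (6 and 2 adjusted over the list alone). The sulfotransferase Sult1d1 rose by 1.90 ± 0.20 in wild type and 1.76 ± 0.20 in the knockout, the pregnane X receptor Nr1i2 by 0.88 ± 0.10 and 0.58 ± 0.10, and the P450 Cyp2c55 fell by 1.53 ± 0.28 in wild type. Aass, of lysine breakdown, rose by 0.96 ± 0.14 and 1.04 ± 0.14, in a list of 26 amino acid genes with 7 higher and 2 lower in wild type and 7 and 0 in the knockout (7 and 4, and 7 and 2, adjusted over the list alone). Of 17 clock genes 4 were higher and 5 lower in wild type and 5 and 3 in the knockout (5 and 5, and 7 and 4, adjusted over the list alone): Nfil3 rose by 1.98 ± 0.18 and 1.92 ± 0.18 and Ciart by 2.83 ± 0.38 and 4.26 ± 0.38, while Nr1d1 fell in both, as given above. Without the 4 arrays with pancreas transcripts the wild-type calls of Mlxipl (-0.69) and Cyp2c55 (-1.76) ended.

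A genomic segment carried along with the Hdac6 mutation could change neighbouring genes in the knockout. Of the nearest 20 measured genes, 10 on each side, 2 had an unadjusted p under 0.05 in the averaged genotype effect, Rbm3 (-0.29) and Pim2 (0.23), against 10% of 17883 other genes (Fisher's exact p = 1), and limma called 0 of the 20. The test gave no sign of such a segment among these genes.

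The genes that can differ between mouse strains, a list of 5, were not called by limma in the averaged genotype effect: Nnt (0.15), Wdfy1 (0.22), Entpd4 (-0.05), Ide (0.16) and Glo1 (-0.09), of which Wdfy1 and Ide had an unadjusted p under 0.05.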
